A study of Mus musculus with 2 samples.

How the data were processed

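RNA sequencing values were analysed for 2 lymphomas of L-DKO mice that were negative for the CD1d tetramer, 1 from a Peyer's patch and 1 from the thymus. Per the labels' protocols, RNA was taken from lysed tumour tissue and made into stranded, poly(A)-selected libraries. The series design text speaks of sorted lymphoma cells, so how pure the tumour cells were is not settled by these sources. Per the submitters' processing notes, TopHat, Cufflinks, Picard and GATK were used with the mouse build mm9. Their versions, the annotation, and the rule by which genes entered the table are not given in the sources used here. Cufflinks is a program that assigns fragments to transcripts by a model, so its values hold no whole read counts.

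Per the file headers, the authors gave 2 kinds of value per library and gene, an FPKM (fragments mapped to a gene, scaled by transcript length and by the mapped fragments of the library) and a standard score. The values deposited under the FPKM header were read as log2(FPKM + 1). No source used here states the base or the added 1, and both were inferred from the values, so each FPKM given rests on that reading. Their maximum was 20.65. The smallest value in the Peyer's patch tumour equals 6.99 steps of double precision on a log2 scale, near a whole number, against 10.09 for the natural logarithm and 23.23 for base 10. The smallest value in the thymic tumour, at 6306 steps on a log2 scale, is printed with too few digits to tell. FPKM on the linear scale was computed from these values. The deposited score is an exact straight line of the log2 value within each library, with residuals of at most 1.2e-08. It was made by the authors with a mean of 3.91 and an SD of 2.84 in the Peyer's patch tumour and 4.54 and 2.43 in the thymic tumour, whereas the deposited genes have a mean of 5.11 and an SD of 2.15 and of 5.20 and 2.00. The authors' scores therefore refer to another set of genes than the table holds. The design had assumed linear FPKM, and the planned threshold applies to the log2 values directly.

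The table holds 8249 genes, all above 0 in both libraries. A gene at exactly 0 in either tumour is therefore not among the values compared, although a few values are almost 0. In the Peyer's patch tumour 117 genes were under 1 FPKM, and in the thymic tumour 25. Without counts the depth of each library is unknown, and no interval for counting error can be given. A 4-fold difference between low values is less certain than between high ones. Spreadsheet software had turned 11 gene symbols into dates, and these were not named. Of all symbols, 7848 (95.1%) matched the names in GENCODE M21, an annotation of another build than mm9. It was used only for gene types, numbers of transcripts, overlaps on the same strand and gene lengths, and no coordinates are given.

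Genes with at least 1 FPKM in at least 1 library were kept, which left out 4. With 1 library per group there is no test and no p-value. Differences are on the log2(FPKM + 1) scale, which understates the change of low genes, and a gene was counted as apart at a difference of at least 2, which is 4-fold. For 51 gene lists of T cell states, cell processes and other cell types, the median difference of the measured members was placed as a percentile among the medians of 10000 random lists of the same size, matched in 20 bins of mean level. Of the lists, 33 had at least 3 measured members, 12 had 1 or 2, for which values alone are given, and 6 had none and were not analysed here. In all 324 of 660 distinct members were measured. A list was called apart outside percentiles 2.5 to 97.5. If genes were independent, 1.65 of the 33 lists would be called by chance. Percentiles describe these 2 libraries, not the tumour sites.

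Named genes followed a fixed rule. It took the 15 largest differences in each direction among genes with at least 10 FPKM in the higher library, without predicted genes, small RNAs or antigen receptor segments. It also took up to 4 members of each list with the largest difference of at least 2, the measured E protein genes, the 10 most abundant genes of each library, and up to 4 members of each T cell or other cell type list with the highest mean. Of these, the text names those that carry each group, and a few genes that the rule took are not reported here. Antigen receptor segments and any list member outside the rule were chosen after their values were seen. The lists, rule, thresholds and alternatives were set before the data were examined.

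Alternatives set then were pseudocounts of 0.1 and 5, no filter or a filter at 5 FPKM, thresholds of 2-fold and 8-fold, and rescaling by the median ratio, the upper quartile or the total. For the lists, unmatched random lists and the mean of the members were also run. Chosen after seeing the data were the authors' standard scores, put back on a log2 scale with the mean of both SDs. They were run for every result that had alternatives, except the correlation across genes. For the lists, rescaling by the total or the upper quartile and removal of the trend with mean level were also chosen then. The steps were tested on simulated data for 8249 genes with a noise SD of 1 per library. Of 200 genes planted with a log2 difference of 4 in this comparison, 90.5% were recovered, and 15.9% of unchanged genes passed the threshold, against 15.7% in theory. A planted list reached percentile 99.97, and 4.5% of random lists fell outside 2.5 to 97.5. The share of unchanged genes that passed follows from the noise SD that was set, and the noise of the real libraries is unknown. Genes were simulated independently, so lists whose genes move together were not covered. The simulation therefore checks the steps and not the calls made below. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.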

Results

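Gene expression was measured by RNA sequencing in lymphomas of L-DKO mice, a strain that the series title ties to high levels of E proteins, the basic helix-loop-helix transcription factors that guide early T cell development. The series as a whole concerns invariant natural killer T (NKT) cells, which recognise lipids presented by CD1d and are stained with CD1d tetramers, and the lymphomas that arise in these mice. The 2 libraries analysed here both came from tumours negative for the CD1d tetramer. The Peyer's patch tumour came from a lymphoid follicle of the gut wall of a 26-week-old mouse, and the thymic tumour from a 30-week-old mouse. Tetramer-positive lymphomas and young, pre-malignant NKT cells were not analysed here. The comparison made was between tetramer-negative tumours from these sites. With 1 library per site, no difference below has a replicate check, and site, mouse and age cannot be separated. Values for 8249 genes were read as log2(FPKM + 1), a scale inferred from the values, and sequencing depth was unknown. Differences are log2(FPKM + 1) in the Peyer's patch tumour minus the thymic tumour.

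Both tumours expressed T cell genes, and 19.9% of all genes tested, T cell genes among them, were at least 4-fold apart. The constant region of the T cell receptor alpha chain, Trac, stood at 1599 FPKM in the Peyer's patch tumour and 1038 in the thymic tumour, and all 19 listed genes of the T cell receptor complex and its signalling were measured in both. The median gene stood at 31.2 FPKM in the Peyer's patch tumour and 32.6 in the thymic tumour. Of the 8245 genes that reached 1 FPKM in at least 1 tumour, 4106 (49.8%) lay within 2-fold and 1637 were at least 4-fold apart. Of these 1637 genes, 646 (39.5%) were higher in the Peyer's patch tumour and 991 (60.5%) in the thymic tumour. This split depended on scaling. With each library rescaled to the same total, 880 genes were higher in the Peyer's patch tumour and 450 in the thymic tumour, and with the authors' standard scores 1218 and 624. Those scalings moved the median difference of all genes from 0.05 to 0.51 and 0.48. Rescaling to the same total also lowered FPKM in both libraries before 1 was added, which shrinks differences of low genes. Mitochondrial transcripts made up 64.3% of the summed FPKM in the Peyer's patch tumour and 72.4% in the thymic tumour, so the sum follows a few genes. The 10 named genes with the highest FPKM in the Peyer's patch tumour were all mitochondrial, led by mt-Ts1 at 816954 FPKM. In the thymic tumour the beta-globin gene Hbb-bs ranked among the 10 highest at 92068 FPKM. Because FPKM is scaled by transcript length, values of very short transcripts are uncertain, and so are the mitochondrial shares of the sum. Across genes the tumours correlated with Pearson's r = 0.69 and Spearman's rho = 0.62, where genes are not independent replicates.

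**Figure D1:**
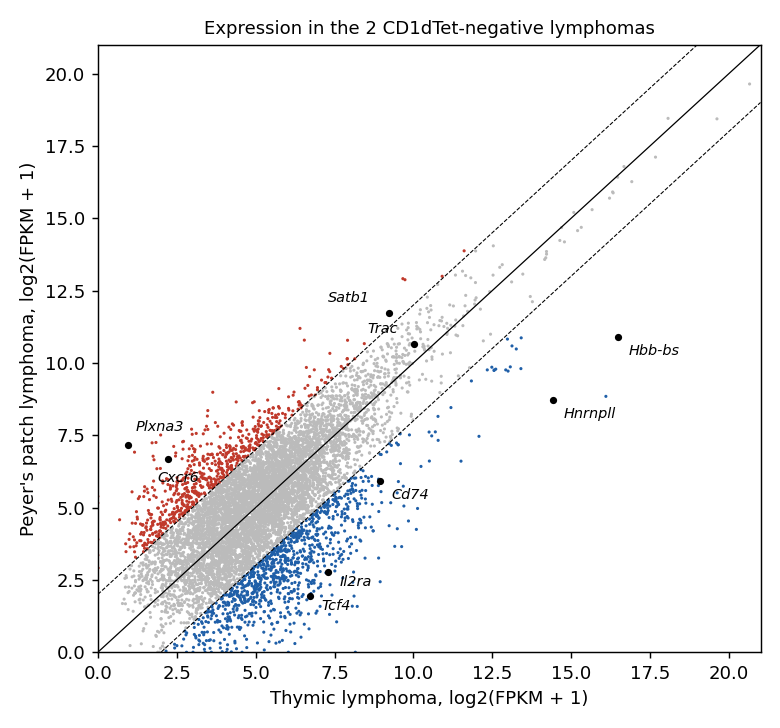
Each point is a gene, with log2(FPKM + 1) in the thymic lymphoma on the horizontal axis and in the Peyer's patch lymphoma on the vertical axis; dashed lines mark 4-fold, red points are the 646 genes at least 4-fold higher in the Peyer's patch lymphoma and blue points the 991 at least 4-fold higher in the thymic lymphoma. With each library rescaled to the same total the counts turn to 880 and 450, while labelled genes such as Hbb-bs at 1916 and 92068 FPKM lie far from the diagonal.

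Of the E protein genes, which the series title refers to, 3 were measured. Tcf3, which encodes E2A, was at 41.0 FPKM in the Peyer's patch tumour and 40.9 in the thymic tumour. Tcf12, which encodes HEB, was at 200.3 and 179.8 FPKM, a difference of 0.15. Tcf4, which encodes E2-2 and is prominent in plasmacytoid dendritic cells and B cells, was at 2.87 FPKM in the Peyer's patch tumour and 105 in the thymic tumour, a difference of -4.78. Of the 3 genes it alone was past 4-fold, as deposited and under each of the 3 alternatives run for these genes. The B cell gene Cd79b (42.9 and 242 FPKM) and 4 of 5 MHC class II genes were also higher in the thymic tumour, and the B cell gene Cd72 (122 and 53.5) was not. The Id genes, whose products inhibit E proteins, were on the fixed list but not among the measured genes, so the genotype was not checked.

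The measured genes of the invariant NKT programme were higher in the Peyer's patch tumour as a group. Of 22 listed genes 12 were measured, and the other members could not be compared. These 12 had a median difference of 2.02, and 0 of 10000 random lists matched on size and mean level reached it. Of the 12 members, 9 were above 0 and 6 were at least 4-fold higher in the Peyer's patch tumour. In the thymic tumour 0 were at least 4-fold higher. Cxcr6, a chemokine receptor of NKT and tissue-resident T cells, was at 101 and 3.64 FPKM in the Peyer's patch and thymic tumours. Il17rb, the receptor for interleukin 25, was at 39.8 and 2.60 FPKM, Egr2 at 206 and 30.1, and Slamf6 at 205 and 31.1. Zbtb16, which encodes PLZF, the factor that directs NKT cell development, was at 37.3 and 9.07 FPKM. Its difference of 1.93 fell short of the threshold of 2 on the scale with 1 added to each FPKM. The 3 members higher in the thymic tumour were Sh2d1a (-0.68), Cd44 (-0.86) and Gata3 (-1.08). Of the 12 members, 10 also belong to another of the fixed lists. Erythroid genes (median -4.02) and MHC class II genes (median -2.23) were lower in the same tumour.

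General T cell genes were also higher in the Peyer's patch tumour as a group. The 19 genes of the T cell receptor complex and signalling had a median difference of 1.26, at percentile 99.92 of matched random lists, with 15 above 0, 4 at least 4-fold higher in the Peyer's patch tumour and 0 at least 4-fold higher in the thymic tumour. The members past 4-fold were the surface protein Cd6 (243 and 22.7 FPKM), the kinase Zap70 (129 and 17.3), the coreceptor Cd4 (109 and 18.8) and Thy1 (305 and 56.9). Erythroid and MHC class II genes were lower in the same tumour, with medians of -4.02 and -2.23, as was the immunoglobulin gene Igkc (-2.78). CD3 chains differed in direction, with Cd3g at 1017 and 341 FPKM and Cd3e at 172 and 561. Both coreceptor genes of CD8 were lower in the Peyer's patch tumour, Cd8a at 4.27 and 9.68 FPKM and Cd8b1 at 17.8 and 55.4, neither past 4-fold. The follicular helper list had 9 measured members, of 17 listed, and a median of 1.22 at percentile 97.8. Tox2 (169 and 25.1 FPKM) and Pdcd1, which encodes PD-1 (32.4 and 5.62), were higher in the Peyer's patch tumour, whereas Cd200 (4.2 and 54.0) and Pou2af1 (26.0 and 192) were higher in the thymic tumour. This list fell to percentile 76.9 when means replaced medians and to 96.7 after the trend with mean level was removed, an alternative chosen after seeing the data. The checkpoint list, with 6 measured members, lay at percentile 97.1, within the range of random lists, and passed the upper bound with unmatched random lists (97.73) or libraries rescaled to the same total (98.14).

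Of the lists of other T cell states, only the regulatory T cell list was called apart. Its 3 measured members, of 10 listed, had a median of -3.09 at percentile 1.14. Il2ra, the interleukin 2 receptor alpha chain, was at 5.91 FPKM in the Peyer's patch tumour and 157 in the thymic tumour. Nrp1 was at 4.95 and 49.7, and Ikzf2 at 11.5 and 16.1. Il2ra and Nrp1 are also expressed outside regulatory T cells, Il2ra in early thymocytes and activated T cells. All 4 measured erythroid genes and 4 of 5 MHC class II genes were higher in the thymic tumour too (medians of -4.02 and -2.23). Which cells gave the regulatory T cell values was not tested. The 14 genes of CD4 CD8 double-positive thymocytes split evenly, 7 above and 7 below 0, with a median of -0.04 at percentile 34.8. Within it the chromatin organiser Satb1 (3383 and 597 FPKM) and the gut-homing receptor Ccr9 (677 and 135) were higher in the Peyer's patch tumour, and Tox (4.40 and 34.5) in the thymic tumour. The 14 homing and egress genes lay at percentile 68.1, with Itgb1, the integrin beta 1 chain, at 9.25 and 57.5 FPKM. The gamma-delta T cell list (3 of 13 listed genes measured) lay at percentile 45.4 and the T helper 2 list (3 of 9) at 70.7. Notch targets (4 of 12) lay at 43.8, and TCF1, LEF1 and Wnt genes (7 of 11) at 91.7. These lists were also within the range of random lists. With few genes that range was wide, from -2.89 to 2.09 for the gamma-delta list, so a moderate shift could not have been called. The cytotoxic list had 1 measured gene, Gzma, at 1813 and 641 FPKM, and the T helper 17 list had Ahr at 2.26 and 4.79.

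**Figure D2:**
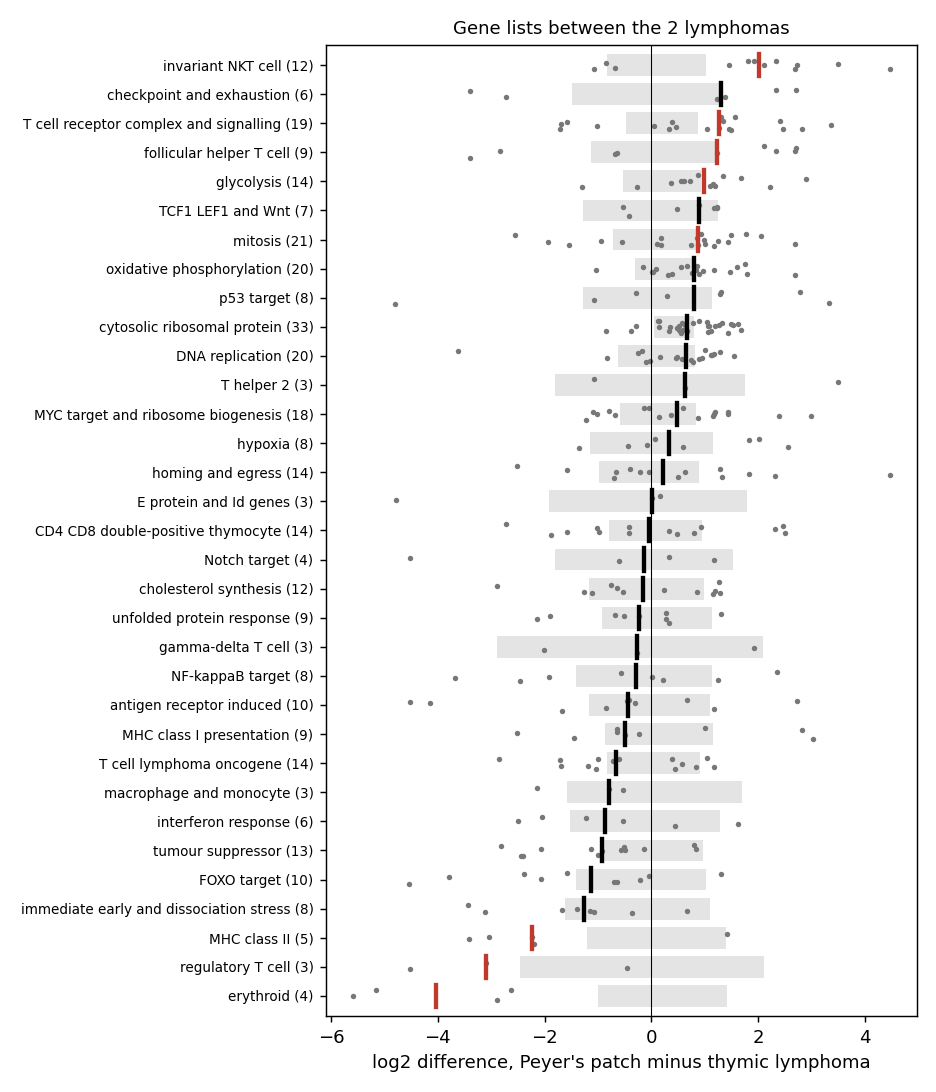
Each row is a fixed gene list with its number of measured genes; dots are its genes' log2 differences, Peyer's patch minus thymic lymphoma, the thick vertical tick is their median and the grey band holds the middle 95% of the medians of 10000 matched random lists. The 8 red ticks lie outside the band, from invariant NKT cell at 2.02 to erythroid at -4.02.

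Genes of blood and antigen-presenting cells were higher in the thymic tumour. All 4 measured erythroid genes, of 11 listed, were at least 4-fold higher there, with a median of -4.02 that 0 of 10000 random lists reached. Hbb-bs was at 1916 FPKM in the Peyer's patch tumour and 92068 in the thymic tumour, where it made up 1.85% of the summed FPKM, and Hba-a1 at 194 and 1444. MHC class II genes, which present peptides on B cells, dendritic cells and macrophages, had a median of -2.23 at percentile 0.16. Of 10 listed, 5 were measured. Of the 5 measured, 4 were at least 4-fold higher in the thymic tumour, among them H2-Aa (45.9 and 502 FPKM) and the invariant chain Cd74 (59.2 and 494), and H2-Ob went the other way (49.1 and 17.8). Of the B cell genes, Cd79b was at 42.9 and 242 FPKM and Cd72 at 122 and 53.5. The 3 macrophage genes, Lyz2 (113 and 504 FPKM), Cd68 (99.5 and 144) and Itgam (64.1 and 111), lay at percentile 11.8, and the neutrophil receptor Cxcr2 was at 10.1 and 84.8 FPKM. Other cell types had 1 or 2 measured genes each. Mybl1 was at 0.892 and 16.1 FPKM and Neil1 at 14.5 and 24.1 (germinal centre B cell), Xbp1 at 23.3 and 37.9 (plasma cell), and Itgb3 at 27.6 and 4.19 (platelet). Epcam was at 65.1 and 59.6 FPKM (intestinal epithelium), Ccl25 at 39.1 and 19.8 (thymic epithelium), Fn1 at 16.0 and 84.8 and Thy1, also a T cell gene, at 305 and 56.9 (fibroblast), and Pecam1 at 157 and 80.3 (endothelium). The Y-linked genes Uty (198 and 637 FPKM) and Ddx3y (6.78 and 13.1) were measured in both tumours.

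**Figure D3:**
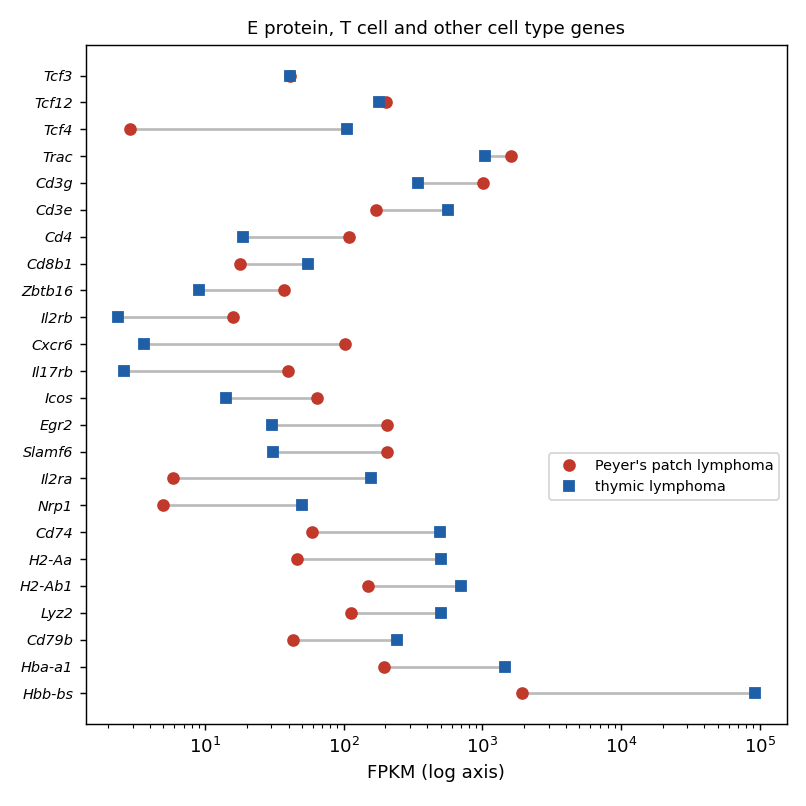
FPKM on a log axis in the Peyer's patch lymphoma (circles) and the thymic lymphoma (squares) for E protein, T cell, NKT and other cell type genes, 1 library per symbol. Cxcr6 lies at 101 and 3.64, Tcf4 at 2.87 and 105, and Hbb-bs at 1916 and 92068.

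Genes of cell division and glucose metabolism were higher in the Peyer's patch tumour, mostly by less than 4-fold. In the same tumour T cell receptor genes were higher (median 1.26), and erythroid and MHC class II genes lower (medians of -4.02 and -2.23). Whether these shifts share a source was not tested. All 21 mitosis genes were measured, with 16 above 0 and a median of 0.87 at percentile 98.0, which dropped to 93.2 with the mean of the members. Bub1, a spindle checkpoint kinase, was at 76.8 and 11.0 FPKM and Aurka at 12.8 and 2.29, while Ccnb1, cyclin B1, was at 10.4 and 66.1. Glycolysis had 12 of 14 genes above 0 and a median of 0.99 at percentile 98.2, or 97.05 after the trend with mean level was removed. Pfkl, a subunit of phosphofructokinase, was at 91.1 and 11.3 FPKM and Gapdh at 1624 and 347. Oxidative phosphorylation lay at percentile 96.5 (18 of 20 genes above 0), with Uqcrc2 at 471 and 72.0 FPKM, and passed the bound with the mean of the members (98.39). DNA replication lay at 93.3 (14 of 20 above 0), with thymidylate synthase, Tyms, at 17.3 and 225 FPKM against the list's direction. Of the 33 cytosolic ribosomal protein genes 30 were above 0 and 0 reached 4-fold. Their median of 0.66 lay at percentile 87.8, and the list passed the bound with the mean of the members (98.94) or unmatched random lists (97.62). MYC target and ribosome biogenesis genes lay at percentile 81.4, with Pes1 at 74.0 and 8.38 FPKM and Ppan at 131 and 24.3. Hypoxia genes lay at 66.8, with Ero1l at 41.6 and 6.18 FPKM, and cholesterol synthesis genes at 42.1.

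Cancer genes fixed as lists did not pass the bounds as deposited. Tumour suppressor genes came close, with 11 of 13 below 0, a median of -0.93 and percentile 2.94. Nf1, a negative regulator of RAS, was at 2.58 FPKM in the Peyer's patch tumour and 24.3 in the thymic tumour, Tet2 at 0.530 and 7.32, Runx1 at 15.2 and 85.4 and Cdkn1b at 5.43 and 25.9. This list passed the bound with the mean of the members (2.31), the authors' standard scores (2.02) or the trend with mean level removed (1.28). Oncogenes of T cell lymphoma lay at percentile 5.03 with 6 of 14 above 0. Among these, Ccnd2, cyclin D2, was at 3.37 and 30.5 FPKM, Myc at 229 and 100.3, and Bcl2 at 123 and 68.9. Genes induced by p53 lay at percentile 90.8. Mdm2 (508 and 73.4 FPKM) and Aen (76.9 and 6.80) were higher in the Peyer's patch tumour and Zmat3 (2.51 and 97.4) in the thymic tumour. FOXO targets had 9 of 10 genes below 0 and a median of -1.14 at percentile 6.59, which became 1.64 with the mean of the members. Pik3ip1 was at 0.959 and 44.7 FPKM, Foxo3 at 2.08 and 41.5 and Foxo1 at 2.01 and 14.7.

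Signalling and stress lists were within the range of random lists, with single members far apart. Antigen receptor induced genes lay at percentile 24.2, with Egr2 at 206 and 30.1 FPKM and Nr4a3 at 1.39 and 41.4. NF-kappaB targets lay at 38.9, with Relb at 3.61 and 57.6 FPKM, Nfkbia at 26.6 and 150.5 and Tnfaip3 at 28.7 and 4.84. Immediate early genes, which cell handling can also induce, lay at 6.02 with 7 of 8 below 0, among them Jund (4.52 and 58.6 FPKM) and Klf6 (0.326 and 10.5). Interferon response genes lay at 11.8, with Gbp2 at 4.98 and 33.0 FPKM, and unfolded protein response genes at 19.5, with Dnajb9 at 8.66 and 41.4. MHC class I presentation lay at 9.38. The immunoproteasome subunit Psmb8 (318 and 38.1 FPKM) and the peptide transporter Tap2 (117 and 15.7) were higher in the Peyer's patch tumour and B2m (2036 and 5572) was higher in the thymic tumour by less than 4-fold.

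The named genes with the widest differences came from many processes. Higher in the Peyer's patch tumour were Plxna3, a semaphorin receptor (142 and 0.955 FPKM), the deubiquitinase Usp33 (120 and 1.24) and Klhl22 (151 and 2.59). Both Diablo and Casp9 of the mitochondrial apoptosis pathway were among them, Diablo at 150 and 2.29 FPKM and Casp9, which encodes caspase 9, at 326 and 10.2. Others of the 15 in this direction were Pdf, Zfp609, Uckl1, Hist1h2ap, Edc4, Wibg, Pdcd2l and Poc1b, with differences from 4.57 for Poc1b to 5.16 for Pdf. Higher in the thymic tumour were Pkib, an inhibitor of protein kinase A (1.48 and 161 FPKM), Qsox1 (0.232 and 74.8), the death receptor gene Tnfrsf10b (0.434 and 85.7) and Hnrnpll, a splicing regulator in T cells (418 and 22027). Zbtb20 was at 0.957 and 92.2 FPKM and the phosphatase Dusp7 at 2.0 and 131. The others were Bloc1s1, Toporsos, Focad, Appl2, Mrgprc2-ps, Hbb-bs, Acpp, Samd15 and Slc25a42, with differences from -5.44 for Slc25a42 to -6.04 for Bloc1s1. Pdf in the thymic tumour and Bloc1s1 in the Peyer's patch tumour were listed at almost 0, which can be a failed estimate. Hnrnpll in the thymic tumour stood above every listed ribosomal protein gene there (Rpl4, the highest, at 7210 FPKM), so its value is uncertain. All 30 genes stayed at least 4-fold apart in the same direction under the 3 alternatives run for them. Hist1h2ap has near-identical copies and is uncertain, and Mrgprc2-ps and Toporsos are a pseudogene and an antisense transcript by name.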

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

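The authors' standard scores and, for the gene lists, rescaling by the total, rescaling by the upper quartile and removal of the trend with mean level were chosen after seeing the data; the other alternatives were set before the data were examined. The count of 1637 genes at least 4-fold apart became 1067 with a pseudocount of 5, 4139 at 2-fold and 583 at 8-fold, as these settings raise the floor or move the threshold. Under the other 7 alternatives it ranged from 1330 to 1842. The 1330 came from rescaling by the total, which also raised the floor, because FPKM fell in both libraries before 1 was added. Rescaling by the total kept 1049 of the 1637 genes, and the standard scores kept 1256; both turned the majority towards the Peyer's patch tumour (66.2% and 66.1% of the genes apart). The correlation across genes of 0.69 was 0.671 with a pseudocount of 0.1 and 0.675 with a filter at 5 FPKM; the cause was not tested. Of the 8 lists called, all 8 kept their call with a pseudocount of 0.1, a filter at 5 FPKM, unmatched random lists, the standard scores and the 3 rescalings. The mean of the members and removal of the trend each kept 6. The invariant NKT, T cell receptor, regulatory T cell, MHC class II and erythroid lists were called under all 9 alternatives. No called list or gene reversed. Among 126 single gene differences, 16 moved by over 1.5-fold or across 4-fold with a pseudocount of 0.1, where Zbtb16 reached 2.03, 1 with the median ratio (Ddit4, 1.94) and 53 with the standard scores. The 30 widest genes stayed apart and 1 of 3 E protein genes did, under each of the 3 alternatives run for them. No paired analysis was possible because each group has 1 library and no test was made; for the same reason no replicate could be left out. Unknown depth limits the low genes most. With genes split into 4 equal sets by mean level, 24.4% of the lowest set and 13.5% of the highest were at least 4-fold apart.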

Other observations

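Histone genes and antigen receptor segments, which the fixed lists did not hold, also differed. All 10 measured genes of the Hist1h2a family, which encode histone H2A and are expressed in S phase, were higher in the Peyer's patch tumour under all 5 scalings, 7 of them at least 4-fold as deposited, with a median difference of 2.88 (range 1.26 to 4.79). Their copies are near-identical and the transcripts largely lack poly(A) tails, so single values are uncertain. Hist1h2ap was at 2340 FPKM in the Peyer's patch tumour and 83.8 in the thymic tumour. The T cell receptor beta segments Trbc1 (167 and 25.7 FPKM) and Trbv13-2 (553 and 52.3) were at least 4-fold higher in the Peyer's patch tumour, while Trbc2 was at 414 and 205. Trbv13-2 encodes V beta 8.2, which is frequent among mouse invariant NKT cells but not confined to them. The alpha segments of their invariant receptor, Trav11 and Traj18, were not among the measured genes. The alpha segments Trav5d-4 (470 and 429 FPKM) and Trav7-6 (57.7 and 56.6) were nearly level. Immunoglobulin transcripts were higher in the thymic tumour, Igkc at 1428 and 9811 FPKM and Ighm at 214 and 716. These genes were chosen after their values were seen.

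Among noncoding RNA genes, a set chosen after the data were seen and not tested against random lists, more were far higher in the thymic tumour than in the Peyer's patch tumour. Of 192 long noncoding RNA genes, 68 were at least 4-fold higher in the thymic tumour and 13 in the Peyer's patch tumour, with a median of -1.01 and 63 genes above 0. With libraries rescaled to the same total the counts were 45 and 17 and the median -0.42, and with the authors' standard scores 55 and 24 and -0.43. The first of these also lowered FPKM before 1 was added, so its counts do not reflect scaling alone. Of 7236 protein-coding genes, 802 were at least 4-fold higher in the thymic tumour and 578 in the Peyer's patch tumour, a split that turned to 338 and 775 with libraries rescaled to the same total. Among 23 small RNA genes 15 were at least 4-fold higher in the thymic tumour and 0 in the Peyer's patch tumour (12 and 1 with that rescaling). The libraries were poly(A)-selected, so these values are uncertain. The small RNA median in the Peyer's patch tumour was 865 FPKM, a value that 3 genes of that library shared. The 23 genes may therefore not be separate measurements.

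Of the tests below, those on overlapping genes and isoforms, on blood, B and myeloid cells and on T cell share were chosen or given their final form after the result was seen. The tests on random loss of molecules and on unspliced sequence were set before their own value was seen, the second after the noncoding RNA counts had been. Several earlier tests were merged, dropped or replaced, because their outcome was fixed by how they were built, because they counted the pattern's own genes, or because their bound lay at a count already seen. No test of scaling was left among them.

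Of all genes tested, 19.9% were at least 4-fold apart, while 0 of 33 ribosomal protein genes, 1 of 20 oxidative phosphorylation genes and 2 of 14 glycolysis genes were. Fragments split between overlapping genes or isoforms are argued against, since 20.8% of the 716 genes with 1 annotated transcript and no overlap on the same strand were at least 4-fold apart (95% Wilson interval 18.0 to 23.9), under an annotation of another build. For highly expressed genes, random loss of molecules that scatters all genes of a level alike is argued against too. The differences of the ribosomal protein genes (medians of 1628 and 947 FPKM) had an SD of 0.59. That lay at percentile 0 of matched random lists, whose median SD was 1.32. Genes of lower level, where a larger share was apart, are not covered by this test, and random loss stays open for them. More unspliced or genomic sequence in the thymic library stays open. Protein-coding genes were split into 4 equal sets by length. The share at least 4-fold higher in the thymic tumour was 13% in the longest set and 9.63% in the shortest. That ratio of 1.35 lay between the bounds set. The share at least 4-fold higher in the Peyer's patch tumour was 6.81% in the longest set and 9.86% in the shortest. Differences between the tumours' clones, sites or ages may also contribute and were not tested.

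Blood and antigen-presenting cell genes were higher in the thymic tumour. Blood, B and myeloid cells in the thymic sample stay open as a source: of 9 B cell and myeloid markers outside those lists 8 were higher there, with a median of -0.78 at percentile 5.50 of matched random lists, between the bounds set. The immunoglobulin genes Igkc (1428 and 9811 FPKM) and Ighm (214 and 716), which the lists do not hold, were higher there too. Cell sorting, which the series design describes, would remove most such cells, whereas RNA from whole tissue would keep them. Expression of MHC class II by the tumour cells themselves was not tested.

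The invariant NKT list was higher in a tumour labelled negative for the CD1d tetramer. A larger share of T cells in the Peyer's patch sample stays open. The 11 members outside the T cell list had a median of 2.11, which exceeds that of the T cell list by 0.85, at percentile 93.94 of random pairs of lists. Erythroid and MHC class II genes were lower in that sample (medians of -4.02 and -2.23). Of the 19 genes of the T cell list 15 were above 0, but they did not move alike (SD 1.51). Their differences ran from -1.71 for Plcg1 to 3.36 for Cd6, with Zap70 at 2.82, Lck at 0.39, Cd3d at 0.06 and Cd3e at -1.70. Trac, outside that list, was at 0.62. No biological explanation was tested, and the tumours' sites and ages, which the labels name, stay open.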
